A study of Mus musculus with 12 samples.

How the data were processed

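Gene expression and chromatin accessibility were measured in single cells of npTh17, pTh17 and Th1 cultures, with 2 RNA and 2 ATAC libraries per condition. Per the labels' protocols, live cells were sorted after 48 h and loaded on the 10x Genomics 5′ kit or the 10x Genomics ATAC kit. The RNA values are UMI counts per gene and cell barcode, made with Cell Ranger 2.2.0 on mm10 per the submitters' processing notes, and were deposited without normalization. The ATAC values are counts of transposase cut sites per peak and barcode, made with Cell Ranger ATAC 1.0.1 on mm10 per the submitters' processing notes, with peaks called in each library apart and barcodes not restricted to cells in the deposited matrices. Other deposited tables list the barcodes, gene identifiers and peak positions. The deposited gene list had 27998 genes and left out T cell receptor and immunoglobulin genes.

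RNA cells were kept with at least 500 genes and under 10% of UMIs from mitochondrial genes, which kept 2234, 2267, 1811, 2042, 2019 and 1420 of 2269, 2294, 2033, 2336, 2151 and 1814 cells (npTh17, pTh17 and Th1, replicates 1 and 2 of each). Total depth per library is given with the results. Scrublet in scanpy 1.11.5 called 85 doublets, which were kept. UMIs were summed per library, and genes were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, 2-sided) on all 6 RNA libraries in 1 fit, with Benjamini-Hochberg (BH) adjustment and a threshold of 0.05; 12488 genes were tested. Comparisons were pTh17 against npTh17, Th1 against npTh17 and Th1 against pTh17, and these share groups, so no overlap between them was computed. TMM factors lay between 0.962 and 1.02 for RNA and between 0.952 and 1.04 for ATAC. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, BH-adjusted over the 26 lists of a comparison. Clusters came from the Leiden method at resolution 0.5 on 30 principal components of 2000 variable genes, with all cells together and no integration. Few-UMI clusters had a median depth under 50% of the library median.

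Peaks of the 6 ATAC libraries were merged where they touched or overlapped, giving 136260 regions, of which 67864 had a peak in every library and were tested, since a library without a peak has no count there. Cut sites were summed over barcodes with at least 1000 of them, and 93.1% to 95.5% of these fell in tested regions. The test was the same as for RNA. Regions were assigned to protein-coding gene spans of GRCm38.p6 that they overlapped, or else to the nearest span within 100 kb, because the annotation at hand gives no strand and so no start sites; 64714 tested regions had a gene. As a check of the build, 65.9% of 21631 genes had a peak within 500 bp of an end of their span, and 31.1% with spans shifted by 50 kb. A planned test of transcription factor motifs, and its variant over shorter sequence, was not run, because the genome sequence was not used here. The share of changed genes with a region changed the same way was compared with other genes by Fisher's exact test.

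Groups, tests, gene lists and the rule for named genes were fixed before the data were examined. For each RNA comparison the rule named the 8 largest rises and the 8 largest falls among genes that passed, had a mean log2 CPM of at least 5 and did not overlap between the groups' libraries. It added 20 genes whatever their result, among them Il17a, Il17f, Il23r, Il22, Il21, Il9, Il10, Maf, Ahr, Ccr6, Csf2, Ifng, Tbx21, Il12rb2, Cxcr3, Gzmb, Foxp3, Bach2 and Tcf7, and up to 4 members per list with the smallest adjusted p. Results of some of these genes are not reported here. For ATAC it named the 4 largest rises and falls among regions, with the same conditions. It added the region with the smallest p at 16 of those loci, up to 84489 bp away. The 26 lists covered helper lineages, published Th17 signatures, interferon responses, cytokines, receptors, metabolism, cell cycle and stress, and 11 marker lists covered T cells and the other cell types that a spleen and lymph node preparation brings; the published signatures were not chosen on these libraries. Shares of cells with a UMI were given for all UMIs and with every cell thinned to 5000 UMIs, with exact 95% binomial intervals. A fold against a group with no counts used a floor of 3 counts over the group, and ratios against 1 to 3 counts carry a 95% counting interval.

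The fits were tested on simulated data drawn from the real means and library sizes for pTh17 against npTh17. With 12299 genes in the step, 47.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, with 12 false calls among 12099 unchanged genes. With 67864 regions the shares were 29.9%, 65.7% and 87.9%, with 33 false calls among 67664. Only 67, 67 and 66 features were changed at these folds, and the rest had a common mean in all conditions. In the real comparison 25.2% of genes and 44.3% of regions were called, so these shares and false calls need not carry over. The biological coefficient of variation was 0.101 for RNA and 0.124 for ATAC. Alternatives were other scaling (DESeq2 size factors, total counts, counts per covered base), other low-count filters, DESeq2 1.42.0, a replicate block, only the 4 libraries compared, other cell and barcode filters, equal cell numbers, no doublets or other cell types, a 2-fold minimum, stricter peak overlap or height, an estimated correlation for camera, a 25 kb limit for genes, 2 UMIs per cell and each library left out in turn. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, statsmodels 0.14.6, igraph 0.11.9, scikit-image 0.26.0, matplotlib 3.10.9 and R 4.3.3 were used.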

Results

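Naive CD4 T cells from mouse spleen and lymph nodes were activated through CD3 and CD28 under 3 sets of cytokine conditions and sorted alive after 48 h. The conditions were non-pathogenic Th17 (npTh17), pathogenic Th17 (pTh17) and Th1, and the labels do not name the cytokines. Th17 cells make interleukin-17 and Th1 cells make interferon-gamma. Each condition had 2 single-cell RNA libraries and 2 separate single-cell ATAC libraries, 12 libraries in all, and the labels do not say whether the 2 are biological or technical replicates. The RNA libraries held 2234, 2267, 1811, 2042, 2019 and 1420 cells after filtering (npTh17, pTh17 and Th1, replicates 1 and 2 of each), with 40234926, 55836760, 31959294, 39588783, 46996043 and 21617560 UMIs. The ATAC libraries held 4379, 5025, 5305, 6123, 4472 and 5278 barcodes with 75818694, 54138357, 118955973, 92619853, 100353357 and 89826163 transposase cut sites in peaks. Values are UMI or cut-site counts of the summed library scaled to its total (CPM), as mean ± SD over the 2 libraries of a condition (n = 2), and positions are on mm10.

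Libraries differed in signs of RNA quality. In the same library order, 1.54, 1.18, 10.9, 12.6, 6.14 and 21.7 percent of the deposited cells had at least 10% mitochondrial UMIs. Of all deposited cells, 8.37, 0.305, 14.5, 8.43, 2.37 and 28.3 percent held under 5000 UMIs. Clusters of cells with few UMIs, described further down, took 20.5, 15.4, 24.8, 23.2, 11.1 and 30.6 percent of the filtered cells. Th1 replicate 2 had the highest of all 3 values, and both pTh17 libraries had more cells of high mitochondrial share than both npTh17 libraries. Of the marker lists of cell types, at least 2 T cell markers were found in 100, 100, 99.8, 99.9, 99.8 and 99.3 percent of the filtered cells. At least 2 markers were found in at most 1.24% for B cells, 0.347% for CD8 T cells, 0.211% for macrophages or monocytes and 0.0704% for plasma cells. For NK, neutrophil or mast, and erythroid or platelet cells, 0 cells had at least 2 markers. Only 1 gamma-delta T cell marker was measured, so these cells could not be counted. Dendritic markers were found in 13.5, 8.87, 18.2, 14.7, 21.1 and 13.5 percent, and this list holds class II genes and Ccl22. Stromal or endothelial markers moved with npTh17, at 4.43, 7.72, 0.442, 0.392, 0.495 and 0.352 percent. That list holds Pdpn, a leading gene of npTh17 clusters, named after its values were seen.

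The comparison of pTh17 with npTh17 asks how the inflammatory and the regulatory forms of Th17 cells differ. Both expressed Il17a and Il17f, the cytokines that define the lineage, and pTh17 had less mRNA of both. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) stood at 618 ± 33.8 CPM in pTh17 and 1777 ± 625 CPM in npTh17 (mean ± SD, n = 2), a log2 fold change of -1.52. Il17f (ENSMUSG00000041872, chromosome 1, 20777146 to 20785274) fell by 1.2 on the log2 scale. The mRNAs of Il22, Il3 and Gzmb were higher in pTh17. Il22 (ENSMUSG00000074695, chromosome 10, 118204584 to 118210047), which acts on epithelia, stood at 284 ± 23.9 against 6.99 ± 6.98 CPM (log2 5.39). Il3, a haematopoietic growth factor, stood at 17.9 ± 3.15 against 0.0585 ± 0.057 CPM (log2 8.33). The protease Gzmb stood at 29.9 ± 9.3 against 0.212 ± 0.223 CPM (log2 7.27). In the opposite direction, Il9 stood at 24.6 ± 4.33 CPM in pTh17 and 1926 ± 617 CPM in npTh17 (log2 -6.29). Maf (ENSMUSG00000055435, chromosome 8, 115703253 to 115706894), a factor that drives Il10, stood at 0.608 ± 0.118 and 63 ± 9.52 CPM (log2 -6.67). Of 12488 genes tested, 3149 changed between pTh17 and npTh17 (edgeR quasi-likelihood test, BH-adjusted p below 0.05), 1537 higher and 1612 lower in pTh17, and 1172 of them at least 2-fold. Among genes with a mean log2 CPM of at least 5, the largest rises beside Il3, Gzmb and Il22 were in Lum, a matrix proteoglycan (146 ± 6.82 against 0.512 ± 0.288 CPM, log2 8.22), the granzyme inhibitor Serpinb9 (log2 5.95) and Serpinb6b (log2 4.92). Next came Serpine2 (log2 4.44) and Tnfsf8, the ligand of CD30 (log2 4.02). The largest falls were in the water and glycerol channel Aqp3 (log2 -9.79), Tmem176a (log2 -7.14), Il9 and Ccl20, the chemokine that binds CCR6 (log2 -4.91). They were followed by Ctla2a (log2 -4.32), lymphotoxin alpha Lta (log2 -3.25), Ass1 (log2 -3.17) and Sfn (log2 -2.67). The count of changed genes was 1619 without npTh17 replicate 2, 2008 without pTh17 replicate 1 and 1738 without pTh17 replicate 2. Single npTh17 libraries set the size of folds against low npTh17 levels. Without npTh17 replicate 1 the rise was 1005-fold (1288 counts against 1, 95% counting interval 180.1 to 39732) for Il3 and 554-fold (2130 counts against 3, 95% counting interval 189 to 2689) for Gzmb, and the log2 value was 7.09 for Il22 and 8.85 for Lum. Without npTh17 replicate 2 it was 7.44, 6.31 and 4.56 for Il3, Gzmb and Il22. Serpine2 stood at 3.73 without pTh17 replicate 2, and Aqp3 at -10.96 and -9.06 without pTh17 replicates 1 and 2. With DESeq2 in place of edgeR the calls of Il22 (adjusted p = 0.087) and Il17a (adjusted p = 0.14) were lost.

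Opposite shifts ran through the Th17 genes. Of the 17 measured genes of the Th17 core list, 4 rose and 12 fell (4 and 12 when adjusted over the list alone; camera, BH-adjusted p = 1.9e-08, and 0.0502 with an estimated correlation). With the estimated correlation the Th17 core call was lost. Ccr6 (log2 -2.01), Il21 (log2 -1.21), Maf and Ahr, a receptor for environmental ligands (log2 -3.72), fell. The interleukin-23 receptor Il23r rose (11 ± 1.05 against 0.835 ± 0.0767 CPM, log2 3.72). Of the 16 genes of a published pathogenic Th17 signature, 15 rose and 0 fell (16 and 0 when adjusted over the list alone; camera, BH-adjusted p = 1.8e-23, and 0.048 with an estimated correlation). Icos, a costimulatory receptor (log2 2.39), Lrmp (log2 1.64), Csf2, the gene of GM-CSF (log2 2.4), and the Th1 factor Tbx21 (log2 2.05, and 2.98 without npTh17 replicate 2) were among those that rose. Of the 7 genes of the published non-pathogenic signature, 0 rose and 6 fell (0 and 6 when adjusted over the list alone; camera, BH-adjusted p = 2.1e-31, and 0.048 with an estimated correlation). Il10 (log2 -3.49) and the Ikaros-family factor Ikzf3 (log2 -2.57) fell beside Il9, Maf and Ahr.

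Genes of other helper lineages moved as well. Of the 21 measured Th1 genes, 13 rose and 4 fell (13 and 5 when adjusted over the list alone; camera, BH-adjusted p = 4.0e-07, and 0.15 with an estimated correlation). Those that rose included the chemokine Ccl5 (log2 3.71), the interleukin-12 receptor chain Il12rb2 (log2 2.99) and the chemokine receptor Cxcr3 (log2 1.36). Ifng itself was not among them, with 3 counts in pTh17 and 0 in npTh17 (edgeR, BH-adjusted p = 0.71). Of 12 regulatory T cell genes, 0 rose and 7 fell (0 and 8 when adjusted over the list alone; camera, BH-adjusted p = 7.3e-11, and 0.048 with an estimated correlation). Foxp3, the regulatory lineage factor, fell from 13.6 ± 5.13 to 0.197 ± 0.0697 CPM (log2 -6.13), with Capg (log2 -2.51), Izumo1r (log2 -2.09) and Ikzf4 (log2 -1.63). Of 14 genes of the response to TGF-beta, a cytokine of regulatory and Th17 differentiation, 1 rose and 7 fell (2 and 9 when adjusted over the list alone; camera, BH-adjusted p = 7.5e-05, and 0.15 with an estimated correlation). Tgfb1 (log2 -1.37), Pmepa1 (log2 -2.23), Ldlrad4 (log2 -2.23) and Skil (log2 -0.90) fell. Of 16 naive and stem-like genes, 8 rose and 3 fell (8 and 3 when adjusted over the list alone; camera, BH-adjusted p = 4.9e-04, and 0.35 with an estimated correlation). Tcf7 rose (log2 0.60) and Bach2 fell (log2 -0.67). Of 12 follicular helper genes, 6 rose and 3 fell (6 and 5 when adjusted over the list alone; camera, BH-adjusted p = 0.022, and 0.30 with an estimated correlation).

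Interferon response, granule, receptor and sterol synthesis genes made further groups. Of 24 interferon-stimulated genes, 11 rose and 1 fell (13 and 1 when adjusted over the list alone; camera, BH-adjusted p = 6.4e-05, and 0.48 with an estimated correlation). The sensor Ifih1 (log2 3.4) and the antiviral enzyme Oas1a (log2 4.71) rose. Of 26 interferon-gamma response genes, 12 rose and 3 fell (15 and 3 when adjusted over the list alone; camera, BH-adjusted p = 9.7e-07, and 0.34 with an estimated correlation). They were led by the guanylate-binding proteins Gbp4 (log2 3.31), Gbp8 (log2 3.16) and Gbp3 (log2 1.99) and by Cd274, the gene of PD-L1 (log2 1.8). Of 13 cytotoxic granule genes, 8 rose and 4 fell (8 and 5 when adjusted over the list alone; camera, BH-adjusted p = 9.5e-04, and 0.37 with an estimated correlation). Serpinb9, Serpinb6b and Gzmb rose, and Ctsw (log2 -7.02) and Ctla2a fell. Of 19 costimulatory and inhibitory receptors, 9 rose and 2 fell (9 and 3 when adjusted over the list alone; camera, BH-adjusted p = 4.9e-05, and 0.35 with an estimated correlation). Tigit rose (log2 3.47) and the ectonucleotidase Nt5e fell (log2 -4.54). Of 10 cytokine feedback regulators, 1 rose and 5 fell (1 and 6 when adjusted over the list alone; camera, BH-adjusted p = 0.0018, and 0.39 with an estimated correlation). Socs2 fell (log2 -2.46). Of 21 sterol synthesis genes, 0 rose and 10 fell (0 and 11 when adjusted over the list alone; camera, BH-adjusted p = 8.4e-04, and 0.43 with an estimated correlation). Mvd was among them (log2 -0.84). Of 28 cell cycle genes, 1 rose and 13 fell (1 and 20 when adjusted over the list alone; camera, BH-adjusted p = 4.8e-04, and 0.44 with an estimated correlation). Ube2c stood at a log2 of -0.60.

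Endoplasmic reticulum chaperones and mitochondrial mRNAs were higher in pTh17 than in npTh17. Of 16 endoplasmic reticulum chaperones, 12 rose and 0 fell (15 and 0 when adjusted over the list alone; camera, BH-adjusted p = 1.2e-07, and 0.39 with an estimated correlation). Hspa5 (log2 1.39), Creld2 (log2 1.17), Sdf2l1 (log2 1.1) and Manf (log2 1.01) rose. Of 13 mitochondrially encoded mRNAs, 7 rose and 0 fell (11 and 0 when adjusted over the list alone; camera, BH-adjusted p = 0.0018, and 0.43 with an estimated correlation). Among them mt-Nd4 stood at a log2 of 0.68. Both groups, and the costimulatory and inhibitory receptors above, were abundant in the few-UMI cells. Their median log2 ratios to the other cells were at least 1.52, 1.58 and 1.42 in every library. Sterol synthesis and regulatory T cell genes, which fell, were abundant there as well, at least 1.21 and 1.22. Without the few-UMI clusters 12 of 12 chaperone calls, 4 of 7 mitochondrial calls and 11 of 11 receptor calls stayed. The few-UMI cells made up 24.8% and 23.2% of the pTh17 cells and 20.5% and 15.4% of the npTh17 cells. Of 16 hypoxia genes, 5 rose and 1 fell (5 and 1 when adjusted over the list alone; camera, BH-adjusted p = 0.035, and 0.64 with an estimated correlation). The hypoxia call was lost without npTh17 replicate 2 or without pTh17 replicate 1. The remaining lists did not pass, but without pTh17 replicate 2 the Th2, chemokine, and immediate-early and heat-shock lists did. Th2 genes were 3 higher and 2 lower of 6 (3 and 2 when adjusted over the list alone; camera, BH-adjusted p = 0.33), although the Th2 factor Gata3 rose (log2 2.54). Oxidative phosphorylation was 0 higher and 1 lower of 34 (0 and 0 when adjusted over the list alone; camera, BH-adjusted p = 0.30). Immediate-early and heat-shock genes were 7 higher and 2 lower of 17 (7 and 2 when adjusted over the list alone; camera, BH-adjusted p = 0.16), with a rise of Fos (log2 1.66). For the other 5 lists median, mean and test differed in sign. Glycolysis was 1 higher and 1 lower of 19 (1 and 1 when adjusted over the list alone; camera, BH-adjusted p = 0.92, median -0.07, mean 0.04, test down). AP-1, BACH and MAF factors were 5 higher and 5 lower of 17 (6 and 6 when adjusted over the list alone; camera, BH-adjusted p = 0.25, median 0.04, mean -0.24, test down). Secreted cytokines were 9 higher and 10 lower of 24 (10 and 11 when adjusted over the list alone; camera, BH-adjusted p = 0.37, median -0.04, mean 0.95, test down). Chemokines and their receptors were 8 higher and 6 lower of 20 (9 and 6 when adjusted over the list alone; camera, BH-adjusted p = 0.33, median -0.10, mean 0.48, test up). The amino acid and integrated stress response was 6 higher and 0 lower of 19 (6 and 0 when adjusted over the list alone; camera, BH-adjusted p = 0.33, median -0.05, mean 0.14, test up).

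**Figure D1:**
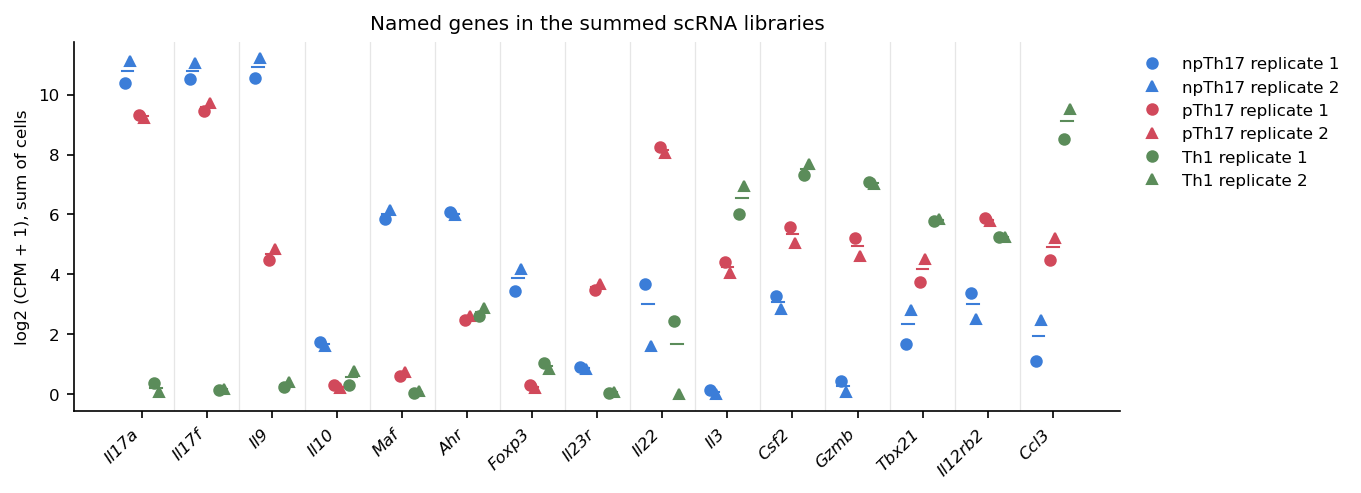
Expression of 15 named genes as log2 of CPM plus 1 in each summed RNA library, with circles for replicate 1, triangles for replicate 2 and a dash at the mean of the group (blue npTh17, red pTh17, green Th1). Il22 and Il23r were highest in the red pTh17 libraries, and Il17a, Il17f and Il9 fell from the blue libraries to the green ones.

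In chromatin, pTh17 and npTh17 differed at cytokine loci. The Il17a region with the smallest p (chromosome 1, 20752417 to 20756199) held 19.6 ± 0.802 CPM of cut sites in pTh17 and 51.9 ± 0.11 CPM in npTh17 (n = 2, log2 -1.41), but per covered base its log2 value was 0.07. The Il17f region (chromosome 1, 20791064 to 20793946, log2 -1.29) was less accessible as well. A region near Csf2 (chromosome 11, 54201178 to 54202528) was more accessible, at 17.2 ± 0.251 against 5.87 ± 0.434 CPM (log2 1.55). Of 67864 regions with a peak in all 6 libraries, 30077 (44.3%) changed between pTh17 and npTh17 (edgeR quasi-likelihood test, BH-adjusted p below 0.05). In pTh17, 14291 of them were more accessible and 15786 less accessible, 8771 at least 2-fold. The split depended on the scaling, with 18872 higher and 12943 lower by total counts and 9401 higher and 11185 lower per covered base. By gene, the tested regions assigned to Il17a were 0 higher and 4 lower of 5, to Il17f 0 higher and 4 lower of 5, and to Il10 0 higher and 8 lower of 11. Those assigned to Maf were 1 higher and 5 lower of 7, to Ahr 0 higher and 9 lower of 13 and to Bach2, a repressor of effector differentiation, 8 higher and 33 lower of 68. Those of Csf2 were 6 higher and 1 lower of 11, of Il12rb2 6 higher and 0 lower of 12, of Gzmb 4 higher and 1 lower of 8, of Tbx21 3 higher and 0 lower of 6, of Il23r 5 higher and 3 lower of 11, of Ccr6 1 higher and 3 lower of 6 and of Cxcr3 2 higher and 1 lower of 4. At Ifng, whose RNA was near 0 in both groups, 6 of 13 regions were more accessible in pTh17 and 1 was less accessible. The one at chromosome 10, 118506047 to 118508216 (log2 1.82) stood at 0.08 per covered base. Among well covered regions the largest rises lay in Vps13d (chromosome 4, 144976761 to 144982603, log2 3.28), Commd1 (log2 2.17) and Stc2 (log2 2.14) and near Acsl6 (log2 1.9). The largest falls lay near Gja5 (chromosome 3, 97003538 to 97009722, log2 -3.92), in Cd101 (log2 -3.36), in Golm1 (log2 -3.28) and at chromosome 1, 128704714 to 128709719, where no gene lay within 100 kb (log2 -2.8). Smaller differences at single regions, the one with the smallest p per locus, of Maf (log2 -0.95), Ahr (log2 -1.46), Bach2 (log2 -1.69), Il10 (log2 -0.98), Tbx21 (log2 0.91), Il12rb2 (log2 1.26), Gzmb (log2 1.42) and Cxcr3 (log2 0.61) passed the test per covered base too. Those at Ccr6 (log2 -0.94) and Foxp3 (log2 -0.41) were lost there, with edgeR adjusted p = 0.070 and 0.072. The Il23r region (chromosome 6, 67490509 to 67492427, log2 1.07) turned to -0.04. The Foxp3 region was also lost without pTh17 replicate 1 (log2 -0.38, edgeR adjusted p = 0.059).

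The comparison of Th1 with npTh17 sets the interferon-gamma lineage against the regulatory form of Th17 cells. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445894) had 20020 counts in Th1 and 0 in npTh17, at least 9344-fold higher against a floor of 3 counts over the group. Its level was 379 ± 323 CPM in Th1 (mean ± SD, n = 2). Replicate 1 had 145 and replicate 2 612 CPM. The rise of Ifng was at least 19585-fold (13221 counts against 0, floor of 3) without Th1 replicate 1 and at least 4633-fold (6799 counts against 0, floor of 3) without Th1 replicate 2. Il17a, Il17f and Il9 stood at 0.167 ± 0.171, 0.124 ± 0.0192 and 0.249 ± 0.102 CPM in Th1, log2 values of -13.05, -13.82 and -13.04 against npTh17. Th1 cells had more Gzmb (131 ± 4.3 against 0.212 ± 0.223 CPM, log2 9.4), more of the chemokine Ccl3 (550.3 ± 265 against 2.89 ± 2.41 CPM, log2 7.51) and more Csf2 (log2 4.62) and Tbx21 (log2 3.73). Between Th1 and npTh17, 4804 of 12488 genes changed (edgeR quasi-likelihood test, BH-adjusted p below 0.05), 2340 higher and 2464 lower in Th1, and 1835 at least 2-fold. Among genes with a mean log2 CPM of at least 5, the largest rises beside Ifng, Gzmb and Ccl3 were in Il3 (log2 10.7), Serpine2 (log2 7.72), Serpinb9 (log2 7.35), the granule gene Nkg7 (log2 5.98) and Serpinb6b (log2 5.98). After Il17f, Il17a and Il9 the largest falls among these genes were in Aqp3 (log2 -10.77), Tmem176a (log2 -9.04), Il21 (log2 -7.6), Ctla2a (log2 -7.32) and Timp1, an inhibitor of matrix proteases (log2 -6.68). Lower in Th1 were also Maf (log2 -9.97), Ahr (log2 -3.51), Ccr6 (log2 -3.6), the cytokine Il10 (log2 -2.36) and the regulatory factor Foxp3 (log2 -3.83). Il23r was higher in npTh17 (18.8-fold, 3 counts against 79, 95% counting interval 6.21 to 93.1). Il12rb2 (log2 2.41) and Cxcr3 (log2 1.12) rose and Bach2 fell (log2 -0.80). Il22 did not pass (log2 -1.33, edgeR, BH-adjusted p = 0.29). Its log2 value was 0.37 without npTh17 replicate 1. Without Th1 replicate 1, which held all Il22 counts of Th1, it passed (edgeR, BH-adjusted p = 0.044), at least 44.7-fold (596 counts against 0, floor of 3) higher in npTh17. It also passed, as lower in Th1, with no low-count filter (log2 -1.36, edgeR, BH-adjusted p = 3.5e-18), with equal numbers of cells (log2 -5.47) and without doublets and other cell types (log2 -2.87). Tcf7 passed narrowly (log2 0.30, edgeR, BH-adjusted p = 0.030). It was lost, with edgeR adjusted p = 0.16, without Th1 replicate 2 (log2 0.22), 0.14 and 0.10 without npTh17 replicates 1 and 2, and 0.062 and 0.054 without pTh17 replicates 1 and 2. The Tcf7 call was also lost with no low-count filter, every deposited cell and equal numbers of cells (edgeR adjusted p = 0.062, 0.065 and 0.057). Without npTh17 replicate 1 the rise was 4486-fold (5512 counts against 1, 95% counting interval 805 to 177200) for Il3 and 2394-fold (8827 counts against 3, 95% counting interval 819 to 11613) for Gzmb, and Ccl3 had a log2 value of 6.88. Left without npTh17 replicate 2, Il3, Gzmb, Ccl3 and Tbx21 stood at 9.81, 8.44, 8.84 and 4.66. Without Th1 replicate 1 the fall was 39680-fold (176344 counts against 1, 95% counting interval 7122 to 1567300) for Il17a, 2876-fold (38341 counts against 3, 95% counting interval 984 to 13945) for Aqp3 and 689-fold (6121 counts against 2, 95% counting interval 191 to 5688) for Maf. The log2 value there was -8.23 for Tmem176a, -8.36 for Il21, -7.99 for Timp1 and -1.58 for Il10. Left without Th1 replicate 2 it was 6.78 for Serpine2, 6.89 for Ccl3, 5.39 for Nkg7, -9.75 for Tmem176a, -6.09 for Timp1 and -3.17 for Il10.

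Interferon response genes rose nearly throughout. Of 24 interferon-stimulated genes, 23 rose and 0 fell (23 and 0 when adjusted over the list alone; camera, BH-adjusted p = 1.3e-15, and 0.31 with an estimated correlation). Isg20, an antiviral exonuclease, stood at a log2 of 5.27 (4.49 without Th1 replicate 1) and Ifih1 at 4.29. Rsad2 was higher in Th1 by 1009.5-fold, 1 count against 721, 95% counting interval 181 to 39929. Of 26 interferon-gamma response genes, 24 rose and 1 fell (24 and 2 when adjusted over the list alone; camera, BH-adjusted p = 1.0e-23, and 0.084 with an estimated correlation). Gbp4 led them (log2 4.8). Of 21 Th1 genes, 14 rose and 2 fell (14 and 2 when adjusted over the list alone; camera, BH-adjusted p = 6.7e-17, and 0.067 with an estimated correlation). Fasl, a death ligand (log2 5.58), rose. Eomes, a T-box factor, was higher by 632-fold, 3 counts against 1355, 95% counting interval 216 to 3070.5. The Eomes rise was 1103-fold (1355 counts against 1, 95% counting interval 198 to 43585) without npTh17 replicate 1 and 397-fold (1355 counts against 2, 95% counting interval 109.8 to 3284) without npTh17 replicate 2. That of Rsad2 was 587-fold (721 counts against 1, 95% counting interval 105 to 23207) without npTh17 replicate 1, at least 141-fold (721 counts against 0, floor of 3) without npTh17 replicate 2 and 613-fold (138 counts against 1, 95% counting interval 108 to 24397) without Th1 replicate 1. Of 17 Th17 core genes, 0 rose and 15 fell (0 and 15 when adjusted over the list alone; camera, BH-adjusted p = 1.2e-38, and 0.019 with an estimated correlation). Of the non-pathogenic signature's 7 genes, 0 rose and 6 fell (0 and 6 when adjusted over the list alone; camera, BH-adjusted p = 3.7e-24, and 0.059 with an estimated correlation). Its member Il1rn stood at a log2 of -4.51. Of the pathogenic signature's 16 genes, 13 rose and 2 fell (13 and 2 when adjusted over the list alone; camera, BH-adjusted p = 3.9e-19, and 0.059 with an estimated correlation). Its member Ccl4 stood at a log2 of 5.38. Of 12 regulatory T cell genes, 4 rose and 7 fell (4 and 7 when adjusted over the list alone; camera, BH-adjusted p = 4.0e-05, and 0.084 with an estimated correlation). Of 14 TGF-beta response genes, 1 rose and 10 fell (1 and 11 when adjusted over the list alone; camera, BH-adjusted p = 4.0e-05, and 0.14 with an estimated correlation).

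Receptor, granule and glycolysis genes changed between Th1 and npTh17 as well. Of 13 cytotoxic granule genes, 7 rose and 4 fell (8 and 4 when adjusted over the list alone; camera, BH-adjusted p = 8.8e-05, and 0.30 with an estimated correlation). Of 20 chemokines and chemokine receptors, 10 rose and 6 fell (11 and 7 when adjusted over the list alone; camera, BH-adjusted p = 0.011, and 0.52 with an estimated correlation). Cxcl10, a ligand of CXCR3, stood at a log2 of 5.59. Of 19 costimulatory and inhibitory receptors, 13 rose and 3 fell (13 and 3 when adjusted over the list alone; camera, BH-adjusted p = 5.9e-05, and 0.31 with an estimated correlation). Cd40lg, a helper signal to B cells, rose (log2 2.4). Of 16 naive and stem-like genes, 10 rose and 3 fell (10 and 3 when adjusted over the list alone; camera, BH-adjusted p = 4.7e-04, and 0.31 with an estimated correlation). Dapl1 (log2 3.63) and Slamf6 (log2 4.18) rose. Of 10 cytokine feedback regulators, 1 rose and 7 fell (1 and 8 when adjusted over the list alone; camera, BH-adjusted p = 0.0012, and 0.31 with an estimated correlation). Socs3, which restrains interleukin-6 signalling (log2 -2.12), and Bcl3 (log2 -2.01) fell. Of 19 glycolysis genes, 1 rose and 13 fell (1 and 13 when adjusted over the list alone; camera, BH-adjusted p = 0.0084, and 0.57 with an estimated correlation). The glucose transporter Slc2a1 (log2 -0.90), the lactate exporter Slc16a3 (log2 -1.0) and Pfkp (log2 -0.84) fell. The glycolysis call was lost without npTh17 replicate 1. Of 24 secreted cytokines, 10 rose and 11 fell (10 and 11 when adjusted over the list alone; camera, BH-adjusted p = 0.045, and 0.31 with an estimated correlation). The cytokine call was lost without any 1 of the 4 libraries of pTh17 and Th1, and the test pointed up without either Th1 library.

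Endoplasmic reticulum chaperones and mitochondrial mRNAs were higher in Th1 than in npTh17. Of 16 chaperones, 11 rose and 1 fell (11 and 1 when adjusted over the list alone; camera, BH-adjusted p = 0.016, and 0.68 with an estimated correlation). Hsp90b1 stood at a log2 of 0.80, and the chaperone call was lost without Th1 replicate 2. Without the few-UMI clusters 10 of 12 chaperone calls, 7 of 8 mitochondrial calls and 15 of 16 receptor calls stayed. Of 13 mitochondrially encoded mRNAs, 8 rose and 0 fell (9 and 0 when adjusted over the list alone; camera, BH-adjusted p = 0.0082, and 0.52 with an estimated correlation). Of these mt-Nd3 stood at a log2 of 1.18. In Th1 replicate 2, 21.7% of deposited cells had at least 10% mitochondrial UMIs and 30.6% of the filtered cells lay in few-UMI clusters, against 6.14% and 11.1% in Th1 replicate 1. The remaining lists did not pass. Th2 genes were 3 higher and 2 lower of 6 (3 and 3 when adjusted over the list alone; camera, BH-adjusted p = 0.96). Cell cycle genes were 2 higher and 15 lower of 28 (2 and 15 when adjusted over the list alone; camera, BH-adjusted p = 0.052). Oxidative phosphorylation was 2 higher and 4 lower of 34 (1 and 2 when adjusted over the list alone; camera, BH-adjusted p = 0.77). Sterol synthesis was 2 higher and 5 lower of 21 (2 and 5 when adjusted over the list alone; camera, BH-adjusted p = 0.57). AP-1, BACH and MAF factors were 5 higher and 6 lower of 17 (5 and 6 when adjusted over the list alone; camera, BH-adjusted p = 0.21). The amino acid and integrated stress response was 2 higher and 4 lower of 19 (2 and 4 when adjusted over the list alone; camera, BH-adjusted p = 0.65). Hypoxia genes were 2 higher and 6 lower of 16 (2 and 6 when adjusted over the list alone; camera, BH-adjusted p = 0.22). Immediate-early and heat-shock genes were 9 higher and 4 lower of 17 (9 and 5 when adjusted over the list alone; camera, BH-adjusted p = 0.25). Follicular helper genes were 5 higher and 4 lower of 12 (5 and 4 when adjusted over the list alone; camera, BH-adjusted p = 0.77), with a median of 0.14, a mean of -0.50 and the test up. The cell cycle list passed without npTh17 replicate 1 or Th1 replicate 1, and the hypoxia list without npTh17 replicate 2.

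Chromatin at the Th17 cytokine genes was less accessible in Th1. At chromosome 1, 20780197 to 20785538, over Il17f, Th1 held 3.86 ± 0.153 CPM and npTh17 64.4 ± 3.02 CPM of cut sites (n = 2, log2 -4.06). The tested regions of Il17a and Il17f were 0 higher and 5 lower of 5 and 0 higher and 5 lower of 5. Near Gzmb (chromosome 14, 56283586 to 56285767) Th1 held 28.6 ± 0.443 against 6.67 ± 0.666 CPM (log2 2.09), with 6 higher and 0 lower of 8 regions. Of 67864 regions with a peak in all 6 libraries, 38379 (56.6%) changed between Th1 and npTh17 (edgeR quasi-likelihood test, BH-adjusted p below 0.05). In Th1, 17685 of them were more accessible and 20694 less accessible, 16667 at least 2-fold. The split depended on the scaling, with 23945 higher and 17890 lower by total counts and 7562 higher and 25082 lower per covered base. Regions of Tbx21 were 5 higher and 0 lower of 6, of Csf2 6 higher and 2 lower of 11 and of Ifng 7 higher and 3 lower of 13. The Ifng region at chromosome 10, 118458361 to 118461910 (log2 1.2) turned to -0.84 per covered base. In the region with the smallest p, Th1 was lower (log2) at Ahr (-3.31, 84489 bp from the gene) and Bach2 (-3.15). Also lower were Il17a (-2.72, 17921 bp), Maf (-2.06, 77608 bp), Ccr6 (-2.0, 8726 bp), Il23r (-1.57), Foxp3 (-1.49) and Il10 (-1.19, 24978 bp). Higher were Csf2 (2.11, 44742 bp), Il12rb2 (1.24), Tbx21 (0.97) and Cxcr3 (0.79, 2746 bp). Whole loci were mixed, with Ahr 1 higher and 9 lower of 13, Bach2 13 higher and 38 lower of 68, Maf 1 higher and 6 lower of 7, Ccr6 1 higher and 3 lower of 6, Il23r 3 higher and 6 lower of 11 and Il10 2 higher and 6 lower of 11. Il12rb2 was 7 higher and 3 lower of 12 and Cxcr3 2 higher and 1 lower of 4, and Foxp3 had 1 tested region. Among well covered regions the largest rises lay in Vps13d (log2 3.84), Stc2 (log2 2.7) and the shared span of Otx1 and Ehbp1 (log2 2.45) and near Acsl6 (log2 2.2). The largest falls lay in Frmd6 (chromosome 12, 70890228 to 70892580, log2 -5.39), at chromosome 1, 128704714 to 128709719 (log2 -5.28), in Wwox (log2 -5.2) and near Gja5 (log2 -4.28).

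**Figure D2:**
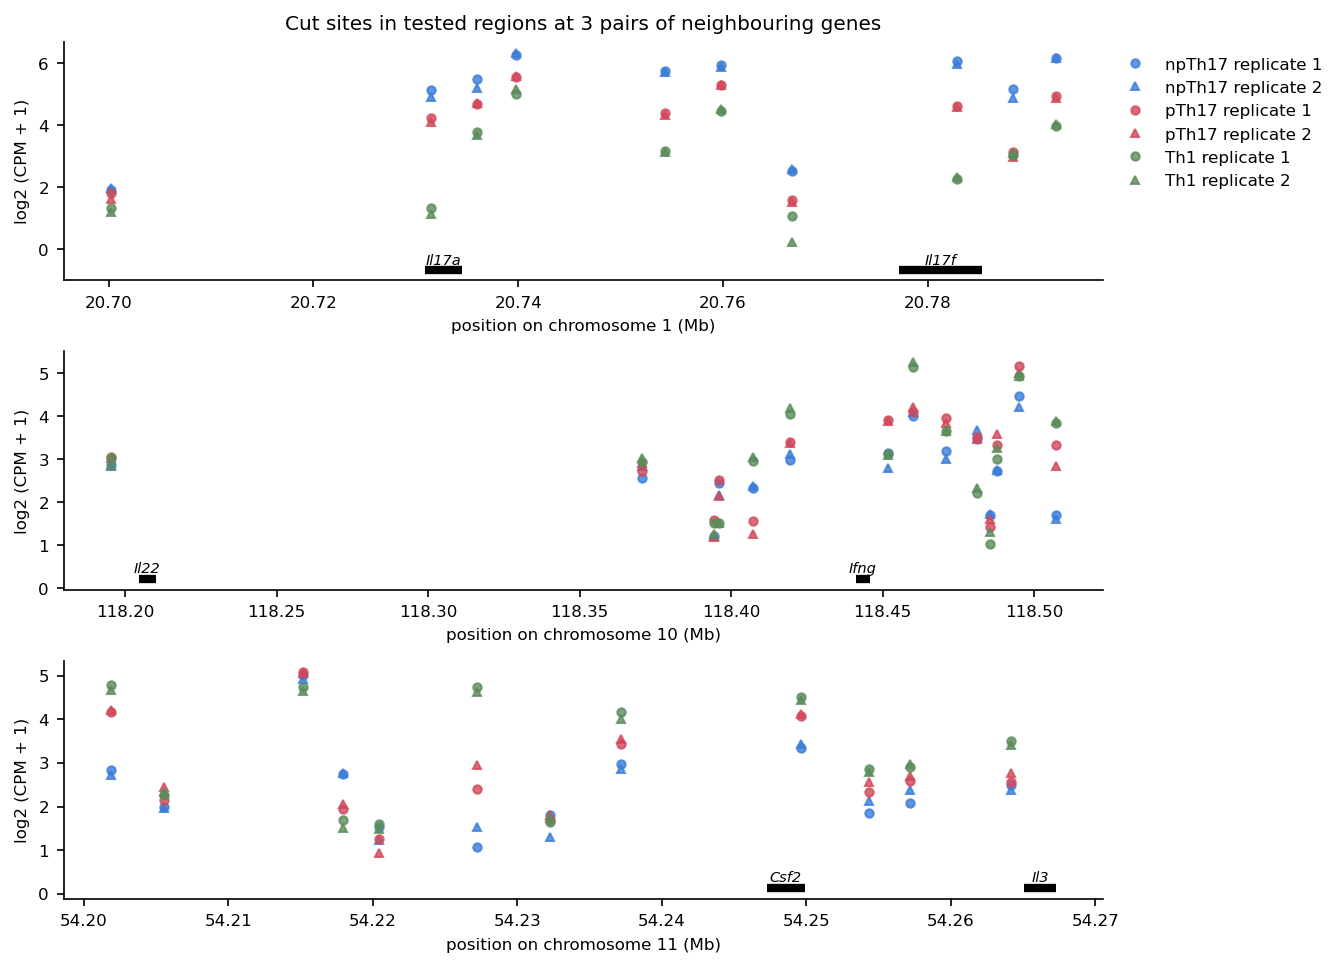
Cut sites as log2 of CPM plus 1 in each tested region, by position in megabases on mm10, at Il17a and Il17f, Ifng and Il22, and Csf2 and Il3, with circles for replicate 1, triangles for replicate 2 (blue npTh17, red pTh17, green Th1) and black bars for gene spans. At Il17f the blue libraries lay above the red and the red above the green (64.4, 23.2 and 3.86 CPM at the region over the gene).

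The comparison of Th1 with pTh17 asks what separates both inflammatory conditions. Ifng had 20020 counts in Th1 and 3 in pTh17, a ratio of 6959 (95% counting interval 2381 to 33746). It stood at 379 ± 323 CPM in Th1 (mean ± SD, n = 2), with 145 in replicate 1 and 612 in replicate 2 when scaled to all UMIs without TMM. The rise was 11551-fold (20020 counts against 1, 95% counting interval 2073 to 456270) without pTh17 replicate 1, 14586-fold (13221 counts against 3, 95% counting interval 4990 to 70738) without Th1 replicate 1 and 3450.3-fold (6799 counts against 3, 95% counting interval 1180.1 to 16735) without Th1 replicate 2. Th17 cytokines were low in Th1. Il17a fell from 618 ± 33.8 to 0.167 ± 0.171 CPM (log2 -11.52), Il17f by a log2 of -12.62, and Il22 from 284 ± 23.9 to 2.22 ± 3.15 CPM (log2 -6.72). Il23r was higher in pTh17 (258-fold, 3 counts against 807, 95% counting interval 88 to 1254). Csf2 (log2 2.21) and Gzmb (log2 2.13), higher in pTh17 than in npTh17, were higher again in Th1. In all, 2157 genes changed between Th1 and pTh17 (edgeR quasi-likelihood test, BH-adjusted p below 0.05), 1021 higher and 1136 lower in Th1, and 898 at least 2-fold. The count was 1057 without pTh17 replicate 1 and 1296 without pTh17 replicate 2. Among genes with a mean log2 CPM of at least 5, the largest rises after Ifng were in the chemokine Ccl3 (log2 4.25), the opioid precursor Penk (log2 4.04) and the costimulatory ligand Cd70 (log2 3.91). They also included the chemokine Ccl4 (log2 3.55), Dapl1 (log2 3.4), Ms4a4b (log2 3.36) and Serpine2 (log2 3.28). Beside Il17f, Il17a and Il22, the largest falls among these genes were in Il9 (log2 -6.76), Il21 (log2 -6.39), Il24 (log2 -5.82), Timp1 (log2 -5.57) and Lum (log2 -5.45). Ccr6 fell (log2 -1.6). Tbx21 rose (log2 1.68), but without pTh17 replicate 1 the call was lost (log2 1.34, edgeR adjusted p = 0.075). Maf fell (log2 -3.29), and without Th1 replicate 1 this was lost (edgeR adjusted p = 0.056), with 6.8-fold (45 counts against 2, 95% counting interval 1.78 to 57.9) more in pTh17. Foxp3 rose (log2 2.29). The Foxp3 call was lost, with edgeR adjusted p = 0.055, 0.11 and 0.14, without pTh17 replicate 1, pTh17 replicate 2 and Th1 replicate 1. Its log2 values there were 2.67, 1.94 and 2.01. With equal numbers of cells it was lost too (log2 2.06, edgeR adjusted p = 0.063). Ahr (log2 0.21), Il10 (log2 1.13), Cxcr3 (log2 -0.23), Bach2 (log2 -0.13), Tcf7 (log2 -0.30) and Il12rb2 (log2 -0.59) did not pass. Of these Il10 passed without Th1 replicate 1 (log2 1.92) and Il12rb2 without npTh17 replicate 1 or 2 (log2 -0.59 in both). With no low-count filter Il12rb2 (edgeR adjusted p = 8.1e-06) and Tcf7 (edgeR adjusted p = 0.042) passed, and Il12rb2 also with only the 4 libraries of both groups (edgeR adjusted p = 0.0060). Without Th1 replicate 1 the log2 value was 4.72 for Penk, -7.14 for Il21, -7.2 for Il24 and -6.87 for Timp1, and the fall was 13556-fold (44865 counts against 1, 95% counting interval 2433 to 535430) for Il17a and at least 2070.2-fold (20555 counts against 0, floor of 3) for Il22. Left without Th1 replicate 2, the log2 value was 2.8 for Penk, 3.65 for Ccl3, 2.36 for Serpine2, -5.99 for Il22 and -4.96 for Timp1. Serpine2 stood at 3.98 without pTh17 replicate 2.

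Every interferon-gamma response gene measured rose in Th1 over pTh17. Of 26 such genes, 26 rose and 0 fell (26 and 0 when adjusted over the list alone; camera, BH-adjusted p = 2.7e-23, and 0.12 with an estimated correlation). Irf8, an interferon-induced factor, stood at a log2 of 2.26, Igtp at 1.56 and the immunoproteasome subunit Psmb9 at 1.15. Of 24 interferon-stimulated genes, 22 rose and 0 fell (23 and 0 when adjusted over the list alone; camera, BH-adjusted p = 3.7e-17, and 0.37 with an estimated correlation). Bst2 was among them (log2 1.13). Of 21 Th1 genes, 13 rose and 0 fell (14 and 1 when adjusted over the list alone; camera, BH-adjusted p = 1.5e-15, and 0.12 with an estimated correlation). Eomes (log2 4.99) and Fasl (log2 3.71) rose. Of 17 Th17 core genes, 0 rose and 12 fell (0 and 13 when adjusted over the list alone; camera, BH-adjusted p = 3.4e-44, and 0.016 with an estimated correlation). Of the pathogenic signature's 16 genes, 10 rose and 3 fell (11 and 4 when adjusted over the list alone; camera, BH-adjusted p = 5.0e-04, and 0.34 with an estimated correlation). Lgals3 fell (log2 -2.53). Of the non-pathogenic signature's 7 genes, 2 rose and 3 fell (2 and 3 when adjusted over the list alone; camera, BH-adjusted p = 0.0019, and 0.37 with an estimated correlation). Its median was 0.21 and its mean -1.56, with the test down. Il6st rose (log2 1.51).

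Genes of glycolysis and of the hypoxia response were lower in Th1 than in pTh17. Of 19 glycolysis genes, 0 rose and 9 fell (0 and 16 when adjusted over the list alone; camera, BH-adjusted p = 1.5e-04, and 0.47 with an estimated correlation). Pyruvate kinase Pkm fell (log2 -0.54, edgeR adjusted p = 0.084 and log2 -0.49 without pTh17 replicate 1). Of 16 hypoxia genes, 1 rose and 9 fell (1 and 9 when adjusted over the list alone; camera, BH-adjusted p = 1.5e-05, and 0.47 with an estimated correlation). Bnip3, a mitophagy receptor (log2 -1.83), Ndrg1 (log2 -2.12), the oxygen sensor Egln3 (log2 -2.2) and P4ha2 (log2 -1.69) fell. Of 21 sterol synthesis genes, 3 rose and 0 fell (3 and 0 when adjusted over the list alone; camera, BH-adjusted p = 0.0061, and 0.54 with an estimated correlation). The sterol call was lost without pTh17 replicate 1 or Th1 replicate 2. Of 16 endoplasmic reticulum chaperones, 0 rose and 5 fell (0 and 7 when adjusted over the list alone; camera, BH-adjusted p = 0.016, and 0.64 with an estimated correlation). That call was lost without pTh17 replicate 1 or Th1 replicate 1. Few-UMI cells, rich in chaperone mRNAs, made up 11.1% of Th1 replicate 1 and 30.6% of Th1 replicate 2, against 24.8% and 23.2% of pTh17. Without their clusters 5 of 5 chaperone calls stayed. Of 13 cytotoxic granule genes, 6 rose and 2 fell (6 and 2 when adjusted over the list alone; camera, BH-adjusted p = 0.0025, and 0.47 with an estimated correlation). Of 20 chemokines and receptors, 9 rose and 3 fell (9 and 3 when adjusted over the list alone; camera, BH-adjusted p = 0.0014, and 0.47 with an estimated correlation). The chemokine call was lost without pTh17 replicate 2, and Ccl9 stood at a log2 of 5.3. Of 12 follicular helper genes, 3 rose and 5 fell (4 and 5 when adjusted over the list alone; camera, BH-adjusted p = 0.016, and 0.37 with an estimated correlation). The follicular helper call was lost without Th1 replicate 1. Of 24 secreted cytokines, 10 rose and 6 fell (12 and 7 when adjusted over the list alone; camera, BH-adjusted p = 0.015, and 0.37 with an estimated correlation). The median was 0.45 and the mean -0.95, with the test down. The call was lost without Th1 replicate 2 and turned up without Th1 replicate 1.

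The other lists did not pass between Th1 and pTh17. Th2 genes were 2 higher and 1 lower of 6 (2 and 2 when adjusted over the list alone; camera, BH-adjusted p = 0.28). Regulatory T cell genes were 3 higher and 4 lower of 12 (3 and 5 when adjusted over the list alone; camera, BH-adjusted p = 0.30), with a rise of the neuropilin Nrp1 (log2 2.94). The TGF-beta response was 1 higher and 2 lower of 14 (1 and 2 when adjusted over the list alone; camera, BH-adjusted p = 0.12). Cell cycle genes were 2 higher and 0 lower of 28 (1 and 0 when adjusted over the list alone; camera, BH-adjusted p = 0.30). Oxidative phosphorylation was 1 higher and 0 lower of 34 (0 and 0 when adjusted over the list alone; camera, BH-adjusted p = 0.44). Feedback regulators were 3 higher and 3 lower of 10 (3 and 3 when adjusted over the list alone; camera, BH-adjusted p = 0.24). AP-1, BACH and MAF factors were 3 higher and 5 lower of 17 (3 and 7 when adjusted over the list alone; camera, BH-adjusted p = 0.40). Costimulatory and inhibitory receptors were 5 higher and 4 lower of 19 (7 and 5 when adjusted over the list alone; camera, BH-adjusted p = 0.24), with a rise of Cd160 (log2 3.75). The amino acid and integrated stress response was 0 higher and 4 lower of 19 (0 and 4 when adjusted over the list alone; camera, BH-adjusted p = 0.064). Mitochondrially encoded mRNAs were 1 higher and 1 lower of 13 (1 and 1 when adjusted over the list alone; camera, BH-adjusted p = 0.63). Naive and stem-like genes were 5 higher and 1 lower of 16 (6 and 5 when adjusted over the list alone; camera, BH-adjusted p = 0.23, median -0.24, mean 0.25, test up). Immediate-early and heat-shock genes were 4 higher and 3 lower of 17 (4 and 3 when adjusted over the list alone; camera, BH-adjusted p = 0.89, median 0.04, mean -0.01, test up). Th2 genes passed without pTh17 replicate 2, the amino acid list without pTh17 replicate 2 or Th1 replicate 1, and the receptors without Th1 replicate 1.

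**Figure D3:**
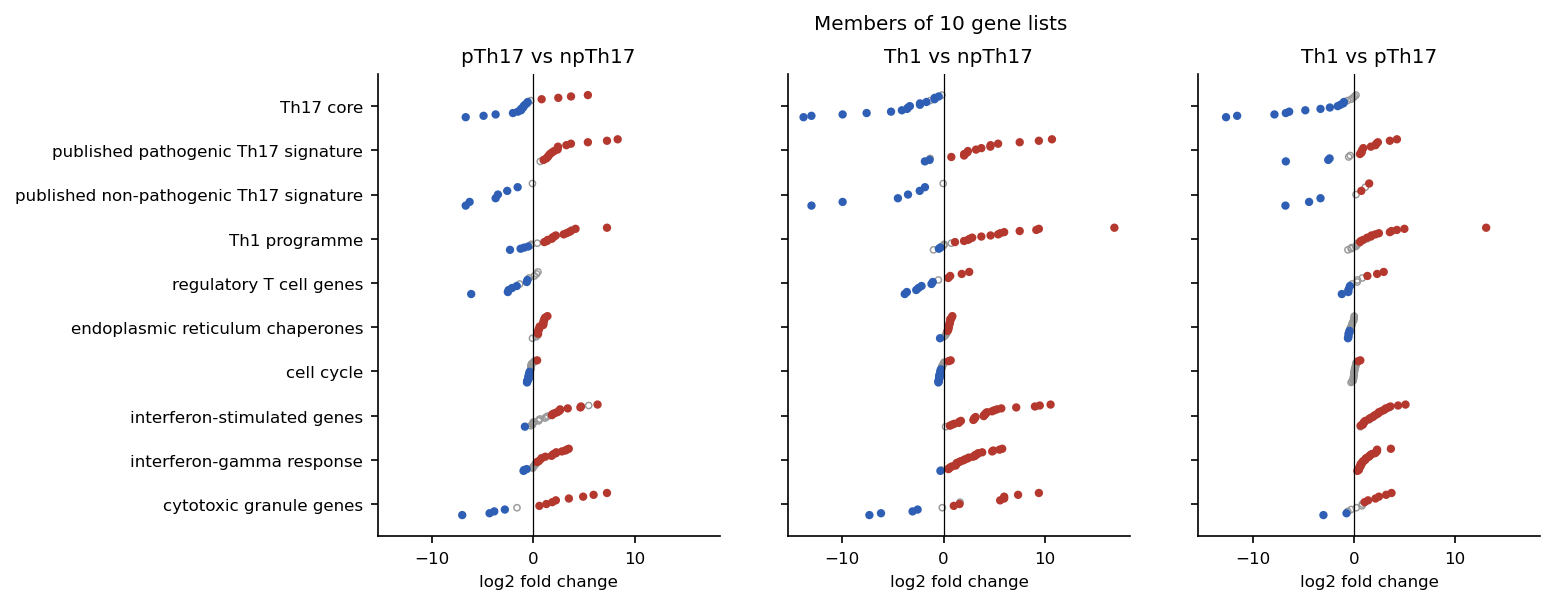
Log2 fold changes of the measured members of 10 gene lists in the 3 comparisons, with filled points for genes with an edgeR adjusted p below 0.05 (red higher, blue lower in the first group named) and open grey points for the rest. Of the interferon-gamma response genes, 12, 24 and 26 of 26 were higher in the 3 comparisons.

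Chromatin of Th1 and pTh17 cells differed at cytokine loci. The region over Il17a (chromosome 1, 20730409 to 20732472) held 1.35 ± 0.216 CPM of cut sites in Th1 and 16.9 ± 1.16 CPM in pTh17 (n = 2, log2 -3.64). Regions of Il17a and Il17f were 0 higher and 4 lower of 5 and 0 higher and 3 lower of 5 (Il17f, log2 -2.59). A region near Csf2 (chromosome 11, 54226183 to 54228292) was more accessible in Th1, at 24.8 ± 1.43 against 5.51 ± 1.7 CPM (log2 2.18). Of 67864 regions with a peak in all 6 libraries, 28091 (41.4%) changed between Th1 and pTh17 (edgeR quasi-likelihood test, BH-adjusted p below 0.05). In Th1, 11702 of them were more accessible and 16389 less accessible, 10518 at least 2-fold. The split depended on the scaling, with 4317 higher and 23337 lower per covered base. At Ifng 4 higher and 3 lower of 13 regions differed, and the one at chromosome 10, 118458361 to 118461910 (log2 1.09) stood at -1.06 per covered base. At Il10 the counts were 6 higher and 1 lower of 11 and at Gzmb 4 higher and 0 lower of 8. Lower in Th1 (log2), in the region with the smallest p, were Il23r (-1.72), Bach2 (-2.13), Ahr (-1.85) and Cxcr3 (-1.24). So were Foxp3 (-1.08), Ccr6 (-1.06), Il12rb2 (-0.94) and Maf (-0.84). Higher by that choice were Il10 (0.71), Gzmb (0.67) and Tbx21 (1.21, -0.32 per covered base). As whole loci, Bach2 was 12 higher and 16 lower of 68, Ahr 5 higher and 4 lower of 13, Il12rb2 5 higher and 4 lower of 12, Ccr6 2 higher and 2 lower of 6, Il23r 3 higher and 5 lower of 11 and Maf 1 higher and 3 lower of 7. Csf2 was 4 higher and 2 lower of 11, Cxcr3 0 higher and 1 lower of 4, Tbx21 2 higher and 0 lower of 6 and Foxp3 0 higher and 1 lower of 1. Among well covered regions the largest rises lay near Elk3 (chromosome 10, 93359158 to 93362350, log2 1.47), Dapl1 (log2 1.44) and Nrip1 (log2 1.32, -0.10 per covered base) and in Eml6 (log2 1.23, 0.07 per covered base, where the call was lost). The largest falls lay in Frmd6 (log2 -4.02) and Optc (log2 -3.41) and near Saysd1 (log2 -3.28) and Vstm5 (log2 -3.27).

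Some peaks were called in both libraries of 1 condition and in no other library. There were 7068 such regions in npTh17, 2048 in pTh17 and 12453 in Th1, against 45 to 385 for the 12 pairs of libraries from different conditions. At Ifng, 6 regions had peaks in Th1 alone and 2 in pTh17 alone, and at Il22 2 had peaks in pTh17 alone. Th1 alone had 3 at Csf2, 3 at Gzmb, 4 at Bach2 and 1 at Ahr. It also had 3 at Il12rb2, 2 at Ccr6, 2 at Cxcr3, 2 at Il23r and 1 at Tbx21. In pTh17 alone there was 1 at Ahr, 1 at Maf and 1 at Il12rb2. npTh17 alone had 9 at Bach2, 5 at Maf, 4 at Ahr and 1 each at Foxp3, Il17a, Il23r, Cxcr3 and Tbx21. A region without a called peak has no count in that library, so no fold was computed for them. The counts depend on the depth and the peak calls of each library. A called peak can hold no cut site of the barcodes kept, as in Th1 replicate 1 at 1 of the 4 Bach2 regions of Th1. This held for 1 or both libraries in 79 of these npTh17, 16 of the pTh17 and 179 of the Th1 regions.

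Changes in RNA and in accessibility went together across genes. Of genes higher in pTh17 than in npTh17, such as Csf2, a larger share had an assigned region that was more accessible in pTh17 than had other genes, 69.1% against 41.4% (odds ratio 3.16, Fisher's exact test, BH-adjusted p = 1.0e-82). Of genes lower in pTh17, such as Maf and Ahr, a larger share had a less accessible region, 65% against 44.6% (odds ratio 2.31, Fisher's exact test, BH-adjusted p = 4.6e-51). For Th1 against npTh17 the shares were 70.8% against 50.05% (odds ratio 2.43, Fisher's exact test, BH-adjusted p = 1.5e-69) for genes that rose, Gzmb among them. For genes that fell, Il17f among them, they were 66.1% against 48.8% (odds ratio 2.05, Fisher's exact test, BH-adjusted p = 1.6e-51). For Th1 against pTh17 they were 71.4% against 38.7% (odds ratio 3.95, Fisher's exact test, BH-adjusted p = 1.1e-84) for genes that rose. For genes that fell, Il17a among them, they were 68.7% against 43.5% (odds ratio 2.85, Fisher's exact test, BH-adjusted p = 7.4e-56). Changed genes had a median of 4 assigned regions and other genes 3, for rises and falls, in pTh17 against npTh17 and in Th1 against pTh17. In Th1 against npTh17 both had a median of 3. A gene with more regions has more chances of a changed one, and the shares were not adjusted for it. Across 11437 genes, the mean log2 change of a gene's regions and its RNA log2 change had Pearson r of 0.371 and Spearman rho of 0.27 (pTh17 against npTh17), 0.355 and 0.262 (Th1 against npTh17) and 0.269 and 0.224 (Th1 against pTh17). Genes are not independent replicates, so these p-values describe genes and not libraries.

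Single cells showed how many cells carried these cytokine mRNAs. Il17f UMIs were found in 81.8% and 88.3% of npTh17 cells (replicates 1 and 2), 34% and 36.8% of pTh17 cells and 0.248% and 0.211% of Th1 cells, which serve as background for the Th17 cytokines. With each cell thinned to 5000 UMIs the shares were 71.3% and 77.3% in npTh17, 27% and 29.5% in pTh17 and 0 in both Th1 libraries. Median depths before thinning were 18804, 25216, 18631, 20351, 24339 and 16298 UMIs per cell in the usual library order. Thinning left out 165, 6, 176, 102, 30 and 261 cells. Il17a UMIs were found in 35.6% and 46.4% of npTh17, 15.7% and 17.3% of pTh17 and 0.0991% and 0.0704% of Th1 cells (thinned 28.6% and 35.4%, 13.1% and 13.8% and 0.0503% and 0%). In the same order, Il9 UMIs were found in 63.4% and 74.9%, 5.08% and 7.69% and 0.248% and 0.282% (thinned 52.5% and 62.5%, 2.87% and 3.87% and 0.101% and 0.173%). Il22 stood at 1.34% and 1.01%, 13.9% and 16.5% and 0.396% and 0% (thinned 0.87% and 0.265%, 10.5% and 13% and 0.352% and 0%). Ifng UMIs were found in 9.91% (95% interval 8.64 to 11.3) and 18% (95% interval 16.1 to 20.1) of Th1 cells. They were found in 0.0552% and 0.049% of pTh17 cells and in 0 npTh17 cells. Thinned, the Th1 shares were 6.54% (95% interval 5.49 to 7.71) and 13.9% (95% interval 12 to 16). Gzmb, lowest in npTh17 (0.269% and 0.132%), stood at 15.4% and 13.1% in pTh17 and 34.4% and 28.3% in Th1 (thinned 0.0967% and 0%, 7.22% and 7.06% and 20.5% and 19.8%). Csf2 stood at 5.64% and 5.69%, 15.4% and 12.6% and 31% and 25.5% (thinned 2.71% and 2.03%, 8.81% and 6.6% and 17.9% and 19%). Intervals are exact binomial and cover counting error only, and with 2 libraries against 2 no exact permutation p can fall under 0.333.

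Some gene pairs shared cells beyond independence. Cells with UMIs of both Il17a and Il17f were 1.14 and 1.08 times as many as independent genes would give in npTh17 and 2.34 and 2.21 times in pTh17 (thinned 1.28 and 1.23, and 2.89 and 2.94). These ratios cannot be compared, since Il17f in 1827 of 2234 and 2002 of 2267 npTh17 cells keeps any ratio there low. Of the Il17a cells, 742 of 796 and 999 of 1051 had Il17f in npTh17 and 226 of 285 and 288 of 354 in pTh17. Ratios for Il17a with Csf2 were 1.6 and 1.4 in npTh17 and 1.09 and 1.08 in pTh17. With Il10 they were 0.515 and 0.73 in npTh17. Ifng with Csf2 shared 63 and 59 Th1 cells (1.02 and 0.904 times). Il17a with Ifng (0 cells in npTh17 and pTh17 and 1 in Th1) decides nothing, with at most 0.198 expected per library.

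**Figure D4:**
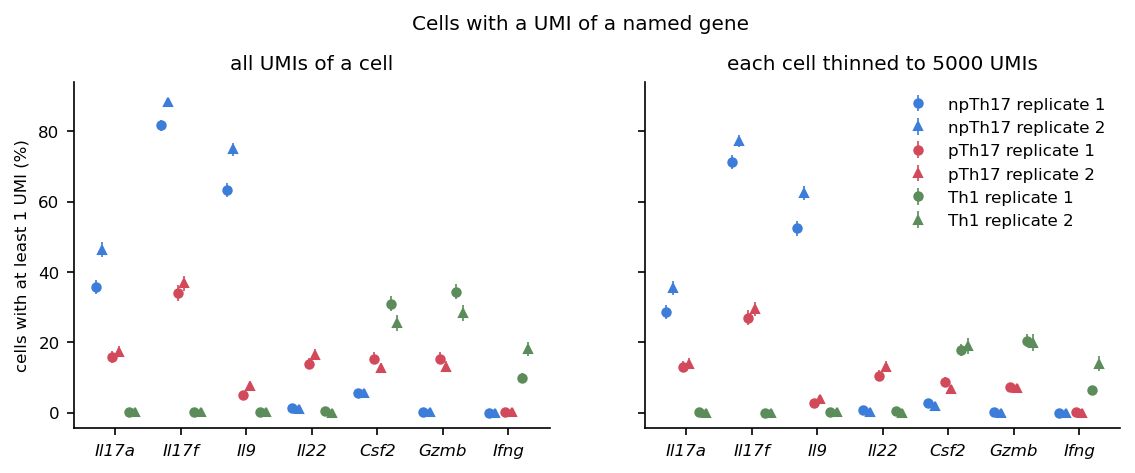
Percent of cells with at least 1 UMI of 7 named genes in each RNA library, with all UMIs on the left and each cell thinned to 5000 UMIs on the right, circles for replicate 1, triangles for replicate 2 and bars for exact 95% binomial intervals (blue npTh17, red pTh17, green Th1). The green Th1 libraries lay above the rest for Csf2, Gzmb and Ifng, and the blue npTh17 libraries for Il17a, Il17f and Il9.

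Clustering of all cells separated the conditions, so cluster sizes were not compared between them. The 10 clusters carry numbers and not names. Clusters 0, 1 and 2 were nearly all npTh17 (cluster 0 held 1228 and 1263 npTh17 cells of replicates 1 and 2). Clusters 3, 4 and 6 were mostly pTh17 (cluster 3 held 642 and 830 pTh17 cells). Clusters 7, 8 and 9 were nearly all Th1 (cluster 8 held 1000 and 459 Th1 cells). Clusters 2, 6 and 9 were few-UMI cells, with medians of 7395, 6309 and 5791 UMIs and mitochondrial shares of 3.83%, 6.0% and 6.28%. Counts of changed genes without these clusters, a check chosen after seeing the data, were 3368 for pTh17 against npTh17, 5045 for Th1 against npTh17 and 2436 for Th1 against pTh17.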

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

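The settings without few-UMI clusters, the list tests without single libraries and the RNA with ATAC comparison per covered base were chosen only after the result was seen. Counts of changed genes and regions stayed within 1.5 times under DESeq2, other size factors and other cell or barcode sets, and those of genes with no low-count filter; the region filters removed no region and so tested nothing. There were 2942, 4386 and 2138 genes by DESeq2 in the order pTh17 against npTh17, Th1 against npTh17 and Th1 against pTh17. DESeq2 kept 2781, 4292 and 1910 of the edgeR calls with their direction, and no RNA call passed in the opposite direction under any setting. A 2-fold minimum, by construction a subset, left 1172, 1835 and 898 genes and 8771, 16667 and 10518 regions. With single libraries left out, which removes samples, the RNA count ranged from 1619 (without npTh17 replicate 2) to 3480 for pTh17 against npTh17, with 2008 and 1738 without pTh17 replicates 1 and 2, and from 1057 (without pTh17 replicate 1) to 1952 for Th1 against pTh17, with 1296 without pTh17 replicate 2; the lone library left in a group was taken to vary like the others. With an estimated correlation 3, 1 and 1 gene lists passed in place of 18, 17 and 14. That test by construction uses only the 3 residual degrees of freedom. In pTh17 against npTh17 the estimate stood at 0.808 for endoplasmic reticulum chaperones and 0.759 for interferon-stimulated genes, far above the preset 0.01. For such lists the p-values at the preset may be too small. For the Th17 core it was -0.0102, and the call was lost without a raised correlation. The parts were not separated by a test. Peaks of at least 50 CPM in 1 group only numbered 406 in npTh17, 68 in pTh17 and 301 in Th1, a subset of taller peaks. Of the values of named genes under all alternatives, 4687 kept their direction and side of the threshold, 117 lost the call, 51 gained one and 3 turned. Of the losses 29 came without pTh17 replicate 1, and DESeq2 ended those of Il22 and Il17a in pTh17 against npTh17. Of those of named regions, 1155 stayed, 7 lost the call and 6 turned. Shares of cells moved by more than the spread of replicates in 102 values and stayed in 6, by construction lower with fewer UMIs or a higher minimum.

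The values that turned were these. Ifng in pTh17 against npTh17, with 3 counts against 0, gave a log2 of 0 with equal numbers of cells and 0 without doublets and other cell types, both of which left pTh17 without counts of it. Il22 in Th1 against npTh17, not called, ranged from -11.01 without Th1 replicate 1 to 0.37 without npTh17 replicate 1. The first is a fitted value against 0 counts, at least 44.7-fold (596 counts against 0, floor of 3), since Th1 replicate 1 held every Il22 count of Th1. The second followed from the npTh17 libraries, since replicate 1 held more Il22 than replicate 2. Why these libraries differed was not tested. It passed, as lower in Th1, with equal numbers of cells (log2 -5.47) and without doublets and other cell types (log2 -2.87), which kept few of its Th1 counts. With no low-count filter it passed at a log2 of -1.36, and the cause was not tested. Per covered base, which divides counts by the width of each library's own peaks, the log2 value turned to 0.0745 at Il17a and -0.0387 at Il23r in pTh17 against npTh17, to -0.84 at Ifng in Th1 against npTh17, and to -1.06 at Ifng, -0.10 at Nrip1 and -0.32 at Tbx21 in Th1 against pTh17; the cause was not tested further. Among all regions it kept 17825, 25518 and 18478 of the calls and turned 602, 1591 and 1416. The odds ratios of RNA with ATAC stayed above 1 within 25 kb and per covered base. The motif test and its alternative were not run.

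With the replicate number as a block, 3966, 5542 and 2900 genes and 29828, 38165 and 28037 regions passed. The labels do not say that equal numbers pair libraries, and deviations of equally numbered libraries from their group means correlated across genes at 0.507, 0.199, 0.175 (npTh17 with pTh17, npTh17 with Th1, pTh17 with Th1) for RNA and at 0.0367, 0.0445, 0.00682 for ATAC. The block ended the calls of the hypoxia list in pTh17 against npTh17 and of the follicular helper and secreted cytokine lists in Th1 against pTh17, and secreted cytokines (pTh17 against npTh17) and the Th2 and amino acid lists (Th1 against pTh17) passed with it. It ended no call of a named gene or region, and Tcf7 passed with it in Th1 against pTh17. Depth limited genes near 0 counts, such as Ifng in pTh17, where no difference was detectable.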

Other observations

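The tests of equal capture of every mRNA, of a few cells with very many Ifng UMIs and of Th1-type cells among the pTh17 cells were chosen only after the result was seen. Receptor and factor mRNAs also differed in how many cells carried them, and the condition with the lowest share gives the background of each. UMIs of Il23r were found in 1.43% and 1.68% of npTh17, 11.8% and 15% of pTh17 and 0.0991% and 0.0704% of Th1 cells (thinned 0.387% and 0.354%, 4.95% and 5.98% and 0% and 0.0863%), where the Th1 libraries give the background. UMIs of Foxp3 were found in 8.42% and 11.9% of npTh17, 0.387% and 0.294% of pTh17 and 1.58% and 0.634% of Th1 cells (thinned 4.01% and 6.02%, 0.0612% and 0% and 0.754% and 0.345%), with pTh17 as background. Il3 stood at 0.0895% and 0.0441% of npTh17, 6.85% and 5.97% of pTh17 and 16.2% and 20.2% of Th1 cells (thinned 0.0483% and 0%, 3.79% and 3.09% and 8.25% and 14.2%), with npTh17 as background.

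Factors of other lineages were not confined to 1 condition. Tbx21 UMIs were found in 3.36% and 10.8% of npTh17, 17.8% and 29.97% of pTh17 and 56.5% and 47% of Th1 cells (thinned 1.01% and 2.83%, 5.5% and 10.5% and 22.9% and 23.5%). Gata3, the Th2 factor, stood at 2.91% and 2.47% of npTh17, 12.5% and 10.7% of pTh17 and 25% and 14.6% of Th1 cells (thinned 0.773% and 0.531%, 4.22% and 3.66% and 7.89% and 6.04%). Median depths per library are those given with the shares of cytokine genes.

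The first pattern was the few-UMI clusters 2, 6 and 9, whose cells were rich in mitochondrial mRNAs (median log2 ratio to the other cells of 1.58 to 2.23 over the 6 libraries) and in mRNAs of membrane and secreted proteins (endoplasmic reticulum chaperones 1.52 to 2.54, costimulatory and inhibitory receptors 1.42 to 2.19, membrane enzymes of sterol synthesis 1.65 to 2.53). A capture loss alike for every mRNA is argued against by the chaperones, at least 1.52 in every library, and a raised sterol and secretory programme by the cytosolic sterol enzymes, at most 0.197 in every library, just under the bound of 0.2 set for them. Loss of cytosolic RNA through a damaged membrane is a candidate, since the glycolytic enzymes stood at -0.0641 or lower in every library. The chaperone part of that test and the whole sterol list had been seen before, while the glycolytic enzymes and the split of the sterol list had not. Resting cells that kept a naive programme cannot be told apart, with naive factors at most 0.41, between both bounds set. A difference between conditions stays open too.

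The second pattern was the Ifng level of the Th1 libraries, 4.23 times higher in replicate 2 than in replicate 1. The greater number of few-UMI cells in replicate 2 is argued against as the whole cause, since without these clusters the ratio was 2.89, although it fell from 4.23, and in these clusters alone it was 4.56. A few cells with very many UMIs are argued against as the whole cause by the shares of cells with an Ifng UMI at equal depth, whose ratio was 2.13 and whose intervals, of counting error only, did not overlap. More Ifng UMIs per positive cell may hold a part, with 6799 UMIs in 200 cells of replicate 1 and 13221 in 256 of replicate 2. Thinning left out 30 cells of replicate 1 and 261 of replicate 2. A difference between the cultures in timing or activation may remain, and no biological explanation was tested, since the design gives no group within Th1.

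The third pattern was the Ifng neighbourhood, where 6 of 13 tested regions were more accessible in pTh17 than in npTh17 while Ifng RNA stood at 0.0432 CPM in pTh17. Th1-type cells among the pTh17 cells are argued against, since the smallest share that gives the accessibility of 1 of these regions, 24.2%, predicts 91.8 CPM of Ifng. Scaling and peak width are too, with 6 of these passing by total counts and 5 per covered base. Spread from neighbouring Il22 is argued against too. Regions facing Il22 had a median log2 change -0.64 relative to the far side (standard error 0.394, 5 against 8 regions). This lay more than 1 but under 2 standard errors below the 0 set against it beforehand. Chromatin opened by the pTh17 conditions ahead of Ifng transcription, which the design names, may account for it and was not tested. Yet 4 of the 6 held more cut sites in pTh17 than in Th1.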
